A study of Mus musculus with 9 samples.

How the data were processed

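The deposited table gives FPKM for 55335 genes in 9 libraries, and the values were used as the authors computed them. Per the labels, total RNA was enriched for mRNA on magnetic beads, fragmented and sequenced on an Illumina NovaSeq6000, and the processing notes name bcl2fastq, HTSeq and DESeq2, without versions, and the mouse build GRCm38. The aligner and the tool that produced the FPKM, and the strandedness of the counting, are not given in the sources used here. Raw reads and counts were not used here. The labels speak of 3 mice per group, and 1 mouse per library is implied but not stated, so the p-values measure the spread between these libraries. Symbols, coordinates and biotypes came from GENCODE M21 on GRCm38, with 55154 genes matched to a symbol and 181 not. The replicate numbers carry no stated meaning. Libraries of MPTP and vehicle mice with the same number deviated together from their group means in all 3 pairs (correlations 0.25, 0.33 and 0.11). For the pairs with running mice the correlations were −0.34, −0.13 and 0.25 against MPTP and −0.26, 0.007 and 0.24 against vehicle. A fit with the number as a block was therefore read beside the results of MPTP against vehicle. Overlaps of exons with other genes were read from the same annotation.

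Gene tests used limma with a mean-variance trend on log2(FPKM + 1), for genes with a mean of at least 0.5 FPKM over all libraries (15997 genes). All 9 libraries entered 1 fit with 3 contrasts (6 residual and 2.68 prior degrees of freedom), with two-sided p adjusted by Benjamini-Hochberg and a threshold of 0.05. A value of 0 for a gene well above 0 elsewhere may be a failed estimate and is written as listed at 0. Lists of cell type, region, state, pathway and quality genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 47 lists with at least 5 tested genes, and again with an estimated correlation and with fry. The preset correlation lets lists of coexpressed genes pass easily, so the p with an estimated correlation stands beside each call. For single lists the limma p were also adjusted over the list alone. The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Of the symbols in the lists, 4 (Fsp1, Cyr61, Bmal1, Park2) had no match.

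Named genes are the 10 largest changes in each direction past the threshold that have an official symbol, a mean of at least 1 FPKM and no overlap between the values of the groups. Where fewer than 5 pass, they are the 5 with the smallest p in each direction, said not to pass. The genes of the study's title, 4 dopaminergic markers and up to 4 members with the smallest p of each list that passed, or 2 of another list, were named as well. The 4 dopaminergic markers and the 2 title genes also have an exact two-sided permutation p over the 20 ways to split 6 libraries, of which the smallest possible is 0.1.

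Fragments per library were estimated from the steps between low FPKM values of 19516 genes with a single transcript over 500 bases, and 37.2% to 39.6% of the low values lay within 2% of a whole step. In simulations (20 runs, noise independent between genes) 200 of 15997 genes were changed, drawn from those with a mean log2(FPKM + 1) above 1. The fit between MPTP and vehicle recovered 85.2% of changes of 1 log2 unit and 98.0% of changes of 2 units, with 4.97% false calls. A list shifted by 0.5 was found in 20 of 20 runs. The recovery rates thus leave out lower genes, and fewer changes than 200 were not simulated. Alternatives changed the filter, the scaling, the variance model, the weights, the threshold, the list test, the libraries used and, after the data were seen, the covariates. The software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.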

Results

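RNA was sequenced from the substantia nigra, the midbrain region that holds the dopaminergic neurons lost in Parkinson disease, of mice in 3 groups of 3. Vehicle mice received saline. The MPTP mice received MPTP, a toxin that damages dopaminergic neurons, at 20 mg/kg on a schedule of 2 injections per week over 5 weeks. The third group received the same injections and had 2 months of voluntary wheel running after the first injection. The deposited table lists 55335 genes in FPKM for 9 libraries, of which 35406 were above 0 in at least 1 library and 15997 had a mean of at least 0.5 FPKM and were tested. If the values were scaled to the counted fragments, the steps between low values place the libraries at about 22000000 to 26700000 fragments. Between 13413 and 13965 genes reached 1 FPKM in a library, and the mitochondrial genome took 29.8% to 32.0% of each library's FPKM. Pearson correlations of log2(FPKM + 1) across genes were 0.966 to 0.982 between libraries of 1 group (9 pairs) and 0.956 to 0.981 between libraries of different groups (27 pairs). Libraries of a group were thus no more alike than libraries of different groups. Values below are mean ± SD over 3 libraries per group, and log2 fold changes are differences of log2(FPKM + 1), which understate the change of low genes.

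The comparison of MPTP with vehicle asks what repeated exposure to the toxin changed. Transcripts of the interferon response and of antigen presentation were higher in MPTP mice. Over all genes 2 single genes passed the test, both higher. H2-K1 belongs to the antigen presentation list, and Igfbp2 to neither list. Igfbp2, a secreted protein that binds insulin-like growth factors, rose from 13.3 ± 0.731 FPKM in vehicle to 25.8 ± 1.54 FPKM in MPTP mice (n = 3 each; log2 fold change 0.91, SE 0.08, limma with Benjamini-Hochberg adjusted p = 0.0211). H2-K1, a heavy chain of the class I major histocompatibility complex (MHC), rose from 5.54 ± 0.359 to 14.7 ± 2.54 FPKM (n = 3 each; log2 fold change 1.26, SE 0.12, limma adjusted p = 0.0265). For both genes all 3 MPTP libraries lay above all 3 vehicle libraries. Igfbp2 (ENSMUSG00000039323) lies on chromosome 1 at 72824503 to 72852474, plus strand, and H2-K1 (ENSMUSG00000061232) on chromosome 17 at 33996017 to 34000347, minus strand (GRCm38), both annotated as protein coding in GENCODE M21. Class I H2 genes are near-identical paralogs, and the assignment of reads among them is uncertain.

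All 28 tested genes of the interferon response were higher in MPTP than in vehicle libraries, with a median log2 fold change of 0.87 (camera adjusted p = 3.45e-33, adjusted p = 0.283 with an estimated correlation). Of these, 18 passed when adjusted over the list alone and 0 over all genes tested (limma, 21 at an unadjusted p under 0.05). Ifi27, an interferon-induced protein of mitochondria, was at 10.6 ± 0.633 FPKM in vehicle and 25.4 ± 5.25 in MPTP mice. Bst2, a membrane protein that tethers budding virus, was at 2.23 ± 0.381 and 14.2 ± 6.73 FPKM. Irf7, a transcription factor of the interferon pathway, was at 0.439 ± 0.0329 and 2.01 ± 0.878 FPKM, and Lgals3bp at 3.88 ± 0.114 and 18.0 ± 11.95 FPKM. All 16 tested genes of antigen presentation were higher (median 0.69, camera adjusted p = 2.53e-30, adjusted p = 0.142 with an estimated correlation). Of these, 14 passed when adjusted over the list alone and 1, H2-K1, over all genes tested. B2m, the light chain shared by class I molecules, was at 71.4 ± 8.18 FPKM in vehicle and 157 ± 33.8 in MPTP mice. H2-Q4 was at 1.89 ± 0.176 and 6.82 ± 2.42, H2-Q7 at 0.207 ± 0.0696 and 1.36 ± 0.302, and Cd74, the invariant chain of class II MHC, at 1.84 ± 0.802 and 5.56 ± 1.31 FPKM. The interferon score (mean log2(FPKM + 1) over the list) was 1.47 ± 0.03 in vehicle libraries and 1.76, 2.42 and 2.77 in MPTP replicates 1, 2 and 3. Without MPTP replicate 1 the count of genes past the threshold went from 2 to 32. Those genes, which lie outside the rule for named genes and were read after their values were seen, included interferon-induced GTPases such as Gbp4 (log2 fold change 2.20, limma adjusted p = 0.000402), Gbp3 (1.72), Irgm1 (1.36) and Igtp (1.94), as well as Tgtp1 and Tgtp2, near-identical copies that read alike.

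**Figure D1:**
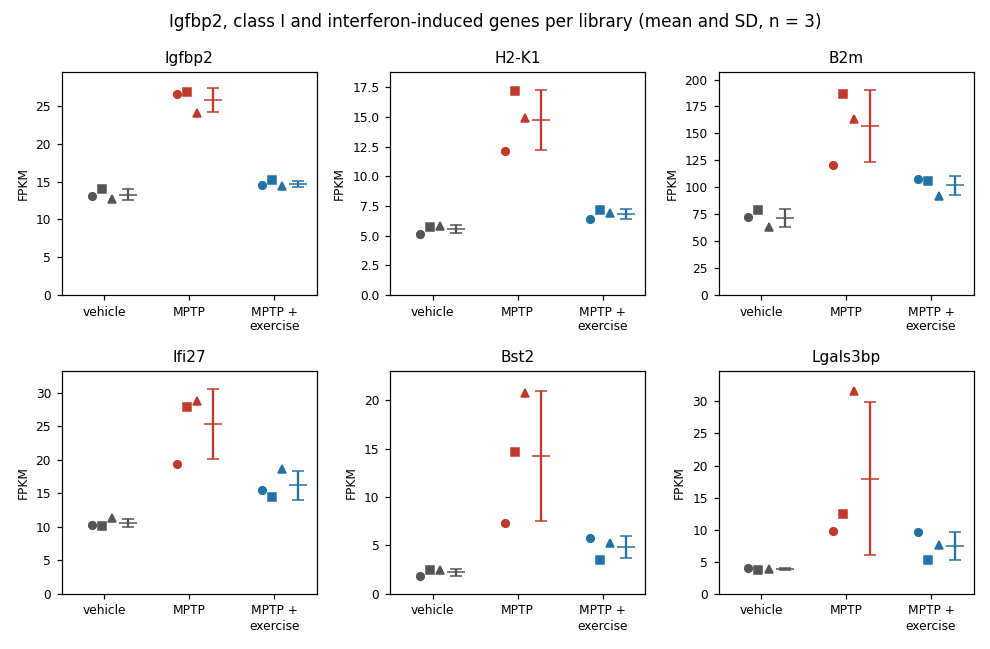
FPKM (y axis, from 0) of Igfbp2, H2-K1, B2m, Ifi27, Bst2 and Lgals3bp in each library by group; circle, square and triangle are replicates 1, 2 and 3, and the bar with error bars is the mean and SD of 3 libraries. In Igfbp2 the MPTP libraries lie at 24.0 to 26.8 FPKM and the other 6 at 12.7 to 15.2 FPKM, and of the genes shown Igfbp2 and H2-K1 passed the test between MPTP and vehicle.

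Genes of microglia, the resident immune cells of the brain, moved in the same comparison. In the activated microglia list 18 of 20 genes were higher in MPTP mice (median 0.20, camera adjusted p = 2.76e-09, adjusted p = 0.0617 with an estimated correlation). Of these, 6 passed when adjusted over the list alone and 0 over all genes tested (limma, 6 at an unadjusted p under 0.05). Its members with the smallest p were B2m, Cd52 (0.618 ± 0.150 and 1.64 ± 0.344 FPKM), Cd74 and the lysosomal protease Ctsd (142 ± 1.13 and 174 ± 4.75 FPKM, counted with an overlapping annotated gene and so uncertain), and B2m and Cd74 are also in the antigen presentation list. In fry, which asks only whether a list moves one way, this list (adjusted p = 0.0161) and antigen presentation (adjusted p = 0.0264) passed and the other 45 did not. The microglia list rose by less (19 of 24 higher, median 0.12, camera adjusted p = 0.000364, adjusted p = 0.617 with an estimated correlation, 1 gene, Ctss, when adjusted over the list alone). Ctss, a cathepsin that trims the class II invariant chain, was at 42.5 ± 5.47 in vehicle and 74.9 ± 13.6 FPKM in MPTP mice. The microglia call ended without vehicle replicate 1 (camera adjusted p = 0.118) and with the choroid plexus score as a covariate (0.358), and the mean of 0.15 went to 0.08 without vehicle replicate 1 and 0.10 without MPTP replicate 2. Complement genes rose as a group (15 of 16 higher, median 0.18, camera adjusted p = 1.48e-05, adjusted p = 0.283 with an estimated correlation). C1qa was at 27.1 ± 3.06 and 36.3 ± 5.60 and C1qb at 27.6 ± 2.001 and 36.7 ± 7.81 FPKM. The complement list shares 4 genes with the microglia list and 2 with reactive astrocytes. The reactive astrocyte list (15 of 19 higher, median 0.13, camera adjusted p = 0.000581, adjusted p = 0.581 with an estimated correlation) had 2 members past the threshold when adjusted over the list alone, H2-D1 (17.0 ± 3.08 and 37.7 ± 7.62 FPKM) and the interferon-induced GTPase Gbp2 (1.65 ± 0.190 and 6.16 ± 3.19 FPKM). Its call ended with array weights (camera adjusted p = 0.110). The reactive astrocyte list shares 2 genes with the interferon response and 1 with antigen presentation, so these lists are not separate responses throughout. Of the cytokine and chemokine list 9 of 10 genes were higher (camera adjusted p = 0.00192, adjusted p = 0.538 with an estimated correlation). Its member Ccl12 was at 0.349 ± 0.184 and 1.42 ± 0.794 FPKM. That call ended with the choroid plexus covariate (0.212), and the mean of 0.22 went to 0.33 without MPTP replicate 1.

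Markers of tissue next to the substantia nigra moved with the MPTP group as well. Of 19 choroid plexus and ependyma genes 17 were higher in MPTP libraries (median 0.57, camera adjusted p = 3.39e-11, adjusted p = 0.538 with an estimated correlation). There, 7 passed when adjusted over the list alone and 0 over all genes tested (limma, 9 at an unadjusted p under 0.05). Clic6 was at 2.27 ± 1.99 and 10.7 ± 4.38 FPKM, Kl at 1.15 ± 0.902 and 7.02 ± 2.84 and Kcne2 at 0.640 ± 0.745 and 5.56 ± 2.12 FPKM in vehicle and MPTP mice. The list score was 1.63 ± 0.39 in vehicle, 2.66 ± 0.49 in MPTP and 1.93 ± 0.73 in running mice, in the same order as the interferon score (1.47 ± 0.03, 2.32 ± 0.51 and 1.76 ± 0.03). All 12 thalamus genes were lower in MPTP libraries (median −0.52, camera adjusted p = 0.0150, adjusted p = 0.697 with an estimated correlation). This call ended with values rescaled to the same sum (0.146), with array weights (0.267) and without MPTP replicate 1 (0.135), MPTP replicate 2 (0.374), vehicle replicate 1 (0.515) or vehicle replicate 3 (0.118). Its mean of −0.57 went to −0.22 without MPTP replicate 2 and −0.18 without vehicle replicate 1, and to −1.08 without MPTP replicate 3 and −1.11 without vehicle replicate 2. Of 6 cholinergic neuron genes 5 were higher (camera adjusted p = 0.00567, adjusted p = 0.581 with an estimated correlation). The choline transporter Slc5a7 was at 1.24 ± 0.382 and 3.84 ± 1.39 FPKM. The call was lost without MPTP replicate 1 (0.131) or vehicle replicate 3 (0.061).

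Energy metabolism and translation genes were slightly higher in MPTP mice. All 47 nuclear-encoded genes of oxidative phosphorylation were higher (median 0.14, camera adjusted p = 8.57e-10, adjusted p = 0.617 with an estimated correlation). Ndufa4 was at 64.0 ± 5.37 and 80.5 ± 14.1 FPKM. Of 40 cytosolic ribosomal protein genes 38 were higher (median 0.17, camera adjusted p = 6.94e-12, adjusted p = 0.581 with an estimated correlation). Rps7 was at 76.6 ± 4.48 and 94.2 ± 12.7 FPKM. In neither list did a member pass when adjusted over the list alone or over all genes tested (limma, 1 and 2 at an unadjusted p under 0.05). Without MPTP replicate 2 their means went from 0.15 to 0.06 and from 0.16 to 0.07. The FPKM sum of a library was 318416 to 319431 in vehicle and 326614 to 347524 in MPTP mice. Such a difference in scale can enter small shifts. Over 25 settings, rescaling to the same sum included, these 0.06 and 0.07 were the lowest means of the 2 lists. The 13 mitochondrially encoded transcripts (11 higher, median 0.12, mean 0.07, camera adjusted p = 0.00161, adjusted p = 0.581 with an estimated correlation) turned direction when values were rescaled to the same sum (mean −0.01) or quantile normalized (mean −0.03). Without mt-Atp6, a gene chosen after its values were seen and low in MPTP replicate 2 and exercise replicate 1 alone, these 3 means were 0.13, 0.05 and 0.01. With values rescaled to the same sum the turn rested on that gene. Quantile normalization gives equal ranks the same value in every library. These transcripts are among the highest, so it holds their shift near 0 by construction and does not test their direction. The call on all 13 ended without MPTP replicate 1 (0.064, mean 0.03) and with no filter on mean FPKM (0.415). Autophagy and lysosome genes (21 of 29 higher, median 0.07, camera adjusted p = 0.00453, adjusted p = 0.538 with an estimated correlation) had a mean of −0.002086 with values rescaled to the same sum. Their call ended without vehicle replicate 3 (0.0743). Nrf2 antioxidant genes (18 of 24 higher, median 0.07, camera adjusted p = 0.0214, adjusted p = 0.691 with an estimated correlation) lost their call without MPTP replicate 1 (0.135), vehicle replicate 2 (0.141) or vehicle replicate 3 (0.224), with values rescaled to the same sum (0.0714) and with genes of at least 5 FPKM (0.192), and their mean of 0.08 went to 0.05 without vehicle replicate 3 and 0.13 without vehicle replicate 1. Endothelial genes (16 of 20 higher, median 0.07, camera adjusted p = 0.00567, adjusted p = 0.691 with an estimated correlation) lost theirs without vehicle replicate 3 (0.118), with array weights (0.0811) and with genes of at least 5 FPKM (0.259). Immediate early genes, which neurons induce on activity, were lower in 26 of 29 cases (median −0.28, camera adjusted p = 0.000385, adjusted p = 0.691 with an estimated correlation). Fos was at 9.45 ± 4.34 and 5.20 ± 2.01 and Dusp1 at 8.74 ± 2.60 and 4.81 ± 1.38 FPKM. The call ended without MPTP replicate 1 (0.187), vehicle replicate 2 (0.225) or vehicle replicate 3 (0.0540), where the mean of −0.32 went to −0.13, −0.14 and −0.18. Without vehicle replicate 1 it went to −0.63.

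Among the lists tied to the study's question, ferroptosis suppressors (20 of 29 higher, median 0.07, camera adjusted p = 0.0796), ferroptosis drivers (13 of 24 higher, median 0.03, camera adjusted p = 0.597), iron handling (11 of 20 higher, median 0.06, camera adjusted p = 0.255) and dopaminergic neurons (14 of 21 higher, median 0.04, camera adjusted p = 0.505) did not pass between MPTP and vehicle. Gpx4, the peroxidase that repairs oxidized membrane lipids, was at 108 ± 5.62 and 138 ± 18.0 FPKM, and in the iron list Hfe, at 1.23 ± 0.0992 and 2.25 ± 0.227 FPKM, was the 1 gene past the threshold when adjusted over the list alone (0 over all genes tested, limma adjusted p = 0.455). Familial Parkinson disease genes split evenly (10 of 20 higher, camera adjusted p = 0.857). The genes with the smallest p on the lower side did not pass either. Insr, the insulin receptor, was at 5.17 ± 0.310 in vehicle and 2.36 ± 0.899 FPKM in MPTP mice (log2 fold change −0.92, SE 0.18, limma adjusted p = 0.508). Hnrnpa3 was at 47.3 ± 3.93 and 23.9 ± 2.54, Uqcc1 at 10.03 ± 1.22 and 5.67 ± 1.60, and the small RNA genes Mir5117 (annotated as a snoRNA) and Mir6993 (a microRNA) at 3.46 ± 2.09 and 0.0233 ± 0.00404 and at 2.30 ± 0.516 and 0.948 ± 0.387 FPKM. Mir5117 shares 84 exonic bases with Gas5 and its value is uncertain.

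Across the 15997 genes, 654 had an unadjusted p under 0.05 between MPTP and vehicle (417 higher, 237 lower), where chance gives 799.85, and the 3 values of each group did not overlap for 1508 genes (9.43%), where chance gives 10%. Of 47 lists, 17 passed camera with its preset correlation (15 higher, 2 lower), 0 with an estimated correlation and 2 in fry. The count of 2 genes became 0 without MPTP replicate 2, MPTP replicate 3 or any 1 of the 3 exercise libraries, which enter the shared estimate of the spread. It became 4 without vehicle replicate 1 (Igfbp2, Pdxp, Prkacb, Gm49510), 3 without vehicle replicate 2 (Igfbp2, B3gnt2, Gm28048) and 1 without vehicle replicate 3 (Gm13054). H2-K1 was past the threshold in none of those 3 fits, and all of these genes but Igfbp2 and H2-K1 were named after their values were seen. The direction of Igfbp2 and H2-K1 held in all 22 settings in which they were refitted, and their calls held in 13 and 10 of them, with adjusted p from 0.00865 to 0.172 and from 0.00212 to 0.224.

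The comparison of MPTP plus exercise with MPTP asks what wheel running changed in mice given the toxin. No single gene passed the test over all genes (limma, 639 at an unadjusted p under 0.05, 177 higher and 462 lower). The interferon, antigen presentation, complement, microglial and choroid plexus groups, which stood high in MPTP mice, were lower in running mice, and so were the genes of blood vessels. None of these lists passed camera with an estimated correlation. Oxidative phosphorylation and ribosomal protein genes, also high in MPTP mice, were not lower. Both comparisons use the MPTP libraries, so a list can move in opposite directions in them with no effect of running. All 16 antigen presentation genes were lower (median −0.59, camera adjusted p = 3.59e-23, adjusted p = 0.191 with an estimated correlation). Of these, 12 passed when adjusted over the list alone and 0 over all genes tested. All 28 interferon genes were lower (median −0.47, camera adjusted p = 2.48e-19, adjusted p = 0.319 with an estimated correlation), 0 when adjusted over the list alone (limma, 15 at an unadjusted p under 0.05).

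In running mice H2-K1 was at 6.83 ± 0.393 FPKM against 14.7 ± 2.54 in MPTP mice (n = 3 each; log2 fold change −0.996, SE 0.12, limma adjusted p = 0.167). H2-Q4 was at 2.27 ± 0.316 against 6.82 ± 2.42, Cd74 at 1.78 ± 0.701 against 5.56 ± 1.31, Bst2 at 4.84 ± 1.17 against 14.2 ± 6.73 and Ifi27 at 16.2 ± 2.18 against 25.4 ± 5.25 FPKM. Igfbp2 came nearest to the threshold, at 14.7 ± 0.408 against 25.8 ± 1.54 FPKM (log2 fold change −0.77, SE 0.08, limma adjusted p = 0.0820). Choroid plexus and ependyma genes were lower in all 19 cases (median −0.55, camera adjusted p = 3.34e-07, adjusted p = 0.552 with an estimated correlation). There, 0 passed when adjusted over the list alone (limma, 4 at an unadjusted p under 0.05), and Clic6 was at 4.16 ± 2.61 and Kl at 2.82 ± 1.94 FPKM in running mice. The choroid plexus mean went from −0.72 to −0.32 without exercise replicate 2 (camera adjusted p = 0.0284), the interferon mean from −0.56 to −0.33 without MPTP replicate 3 and the microglia mean from −0.11 to −0.0553 without MPTP replicate 2, −0.0546 without exercise replicate 2 and −0.17 without MPTP replicate 1. Complement (15 of 16 lower, median −0.23, camera adjusted p = 5.05e-06, adjusted p = 0.191 with an estimated correlation), activated microglia (16 of 20 lower, median −0.09, camera adjusted p = 0.00137, adjusted p = 0.191), reactive astrocytes (14 of 19 lower, median −0.20, camera adjusted p = 0.000864, adjusted p = 0.537) and microglia (19 of 24 lower, median −0.10, camera adjusted p = 0.0145, adjusted p = 0.769) passed as well, the second p of each with an estimated correlation. C1qa was at 28.6 ± 0.820 FPKM in running mice, and Cd74 was the 1 gene of the activated microglia list past the threshold when adjusted over the list alone. Some of these lists share genes, as given for MPTP against vehicle. Without MPTP replicate 2 the calls of activated microglia (0.175), reactive astrocytes (0.0871) and microglia (0.676) ended. With array weights the same 3 ended (0.0623, 0.0656 and 0.765). The reactive astrocyte call also ended at a mean of at least 5 FPKM (0.819, mean −0.06 against −0.21), and that of microglia without exercise replicate 2 (0.513) and with the choroid plexus covariate (0.438). MPTP replicate 2 and exercise replicate 2 were the lowest in Slc6a3, the dopamine transporter, at 0.0377 FPKM and listed at 0. Exercise replicate 1, next at 0.149 FPKM, was kept, since 1 exercise library would be left without it. Without the first 2, the calls of complement (0.0551) and of activated microglia (0.299), reactive astrocytes (0.143) and microglia (0.615) ended, while the antigen presentation, interferon, endothelial, mural and choroid plexus calls held.

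Vessel genes were lower in running mice than in MPTP mice. All 20 endothelial genes were lower (median −0.24, camera adjusted p = 2.03e-13, adjusted p = 0.191 with an estimated correlation). Of these, 8 passed when adjusted over the list alone and 0 over all genes tested (limma, 10 at an unadjusted p under 0.05). Pecam1, a junction protein of endothelium, was at 4.02 ± 0.358 in MPTP and 2.81 ± 0.443 FPKM in running mice, Cdh5 at 4.63 ± 0.517 and 3.33 ± 0.168, and the tight junction protein Cldn5 at 17.7 ± 0.835 and 13.3 ± 1.76 FPKM. All 20 genes of mural and fibroblast-like cells, which surround the vessels, were lower (median −0.36, camera adjusted p = 1.02e-10, adjusted p = 0.260 with an estimated correlation). There, 2 passed when adjusted over the list alone, Pdgfrb (4.92 ± 0.210 and 3.66 ± 0.264 FPKM) and Vtn (24.9 ± 3.22 and 17.9 ± 1.36 FPKM), and 0 over all genes tested. Genes of blood cells were lower beside them in all 8 cases (median −0.93, camera adjusted p = 1.95e-06, adjusted p = 0.241 with an estimated correlation). There, 3 passed when adjusted over the list alone, the neutrophil genes S100a8 (1.35 ± 0.272 and 0.155 ± 0.170 FPKM), S100a9 (3.98 ± 0.995 and 0.810 ± 0.603) and Ngp (1.01 ± 0.448 and 0.174 ± 0.0320), and 0 over all genes tested. All 5 genes of border macrophages and monocytes were lower (median −0.19, camera adjusted p = 0.00136, adjusted p = 0.191 with an estimated correlation), and Cbr2 passed when adjusted over the list alone. Without MPTP replicate 2 and exercise replicate 2 the blood (0.0552) and border macrophage (0.186) calls ended, and the second also ended with the choroid plexus covariate (0.0566). Vegfa, a growth factor for vessels in the exercise and neurotrophic list, was at 15.2 ± 0.921 in MPTP and 11.9 ± 0.573 FPKM in running mice, and that list did not pass (15 of 24 lower, camera adjusted p = 0.489).

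**Figure D2:**
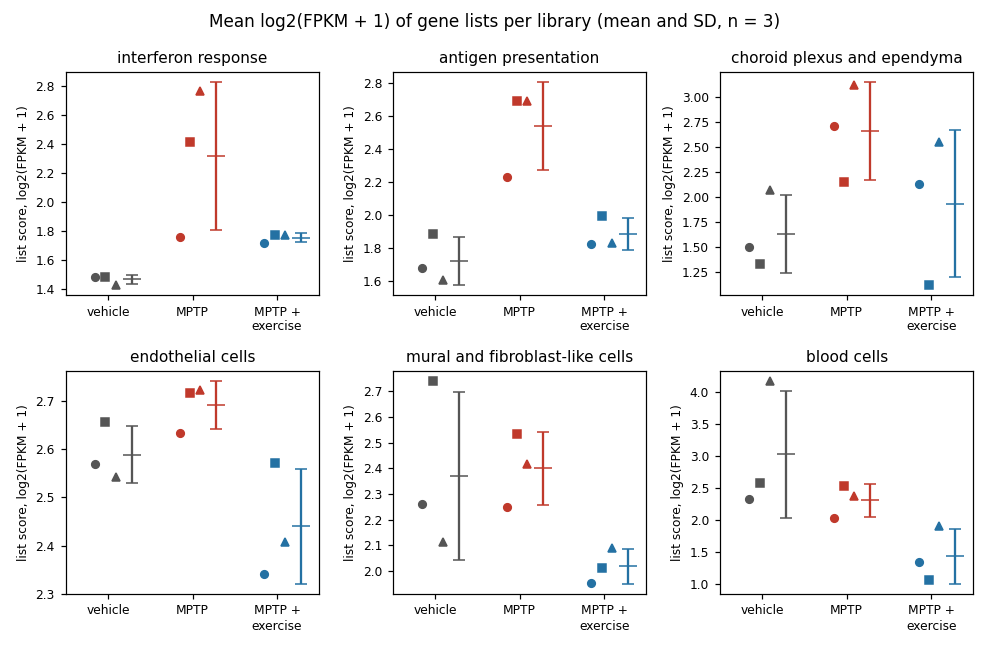
List score (y axis, mean log2(FPKM + 1) over the genes of a list) per library for 6 lists by group; circle, square and triangle are replicates 1, 2 and 3, and the bar with error bars is the mean and SD of 3 libraries. The endothelial scores were 2.69 ± 0.05 in MPTP and 2.44 ± 0.12 in running mice, and the interferon score of MPTP replicate 1, at 1.76, lies within the 1.72 to 1.78 of the running mice.

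Other groups were higher in running than in MPTP mice. Heat shock genes rose as a group (15 of 18 higher, median 0.15, camera adjusted p = 7.07e-06, adjusted p = 0.319 with an estimated correlation). Hsp90aa1 was at 252 ± 7.60 in MPTP and 291 ± 14.1 FPKM in running mice. The call ended with the choroid plexus covariate (0.514), and the mean of 0.13 went to 0.07 without exercise replicate 2. Genes induced by glucocorticoids were higher in 20 of 23 cases (median 0.14, camera adjusted p = 1.63e-05, adjusted p = 0.241 with an estimated correlation). Ddit4 was at 15.1 ± 3.01 and 23.1 ± 3.26 and the clock gene Per1 at 7.48 ± 0.918 and 9.98 ± 1.66 FPKM. The mean of 0.16 went to 0.08 without MPTP replicate 1 and 0.11 without exercise replicate 3. Immediate early genes were higher in 26 of 29 cases (median 0.27, camera adjusted p = 1.87e-05, adjusted p = 0.701 with an estimated correlation). Dusp1 was at 4.81 ± 1.38 and 6.90 ± 0.869 FPKM. The call ended without MPTP replicate 1 (0.0983) or exercise replicate 1 (0.111), where the mean of 0.30 went to 0.11 and 0.12. Without exercise replicate 2 it went to 0.46. Non-polyadenylated RNAs, which a bead enrichment of mRNA should deplete, were higher in 7 of 10 cases (median 0.18, camera adjusted p = 0.00136, adjusted p = 0.502 with an estimated correlation). Rpph1, the RNA of ribonuclease P, passed when adjusted over the list alone at 0.152 ± 0.107 and 1.21 ± 0.333 FPKM. It shares 233 exonic bases with Ccnb1ip1, so its value is uncertain. The mean of the list, 0.28, went to 0.15 without MPTP replicate 2, 0.10 without exercise replicate 1 and 0.43 without exercise replicate 2. In none of the first 3 lists did a gene pass when adjusted over the list alone (limma, 2, 4 and 0 at an unadjusted p under 0.05). Small positive shifts in cholesterol synthesis (21 of 22 higher, median 0.07, camera adjusted p = 0.000417, adjusted p = 0.701 with an estimated correlation), oxidative phosphorylation (38 of 47, median 0.06, 0.000894 and 0.769), ribosomal proteins (31 of 40, median 0.06, 0.00565 and 0.769) and synaptic vesicle genes (20 of 27, median 0.07, 0.0197 and 0.701) also passed camera. Leaving out 1 library ended each of these calls. The cholesterol mean went to 0.04 without MPTP replicate 3 (camera adjusted p = 0.147) and −0.02 without exercise replicate 2 (0.810). The oxidative phosphorylation mean went to −0.01 without MPTP replicate 3 (0.943) and 0.02 without exercise replicate 2 (0.333). The ribosomal mean went to −0.001711 without MPTP replicate 1 (0.673), 0.01 without MPTP replicate 3 (0.670) and 0.005627 without exercise replicate 1 (0.707). The synaptic vesicle call ended without MPTP replicates 1 (0.287) or 3 (0.162) and exercise replicates 1 (0.134) or 3 (0.157). Other settings ended these calls too. With array weights the cholesterol mean went to 0.02 (0.157). With quantile normalization the oxidative phosphorylation (0.275), ribosomal (0.412) and synaptic vesicle (0.275) calls ended. With the choroid plexus covariate the cholesterol mean turned to −0.08 (0.234) and the oxidative phosphorylation mean to −0.07 (0.0207), and the ribosomal (0.255) and synaptic vesicle (0.234) calls ended. The last also ended at a mean of at least 5 FPKM (0.0931) and with the hippocampus covariate (0.147). In the other direction, the cholesterol mean of 0.10 went to 0.18 without exercise replicate 3. The oxidative phosphorylation and ribosomal means, 0.06 and 0.05, went to 0.15 each without MPTP replicate 2, the first to 0.11 without exercise replicate 3 and 0.04 without MPTP replicate 1 and the second to 0.09 without exercise replicate 2. The synaptic vesicle mean of 0.06 went to 0.01 without MPTP replicate 1, 0.04 and 0.02 without exercise replicates 1 and 3, and 0.13 and 0.12 without MPTP and exercise replicates 2.

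Ferroptosis suppressors (20 of 29 lower, median −0.04, camera adjusted p = 0.489) and drivers (14 of 24 lower, camera adjusted p = 0.866) did not pass between running and MPTP mice, and for the drivers the median (−0.02) and the mean (0.01) differed in sign. The dopaminergic list did not pass either (13 of 21 lower, median −0.02, camera adjusted p = 0.844, with the test pointing up). Of the genes with the smallest p on the higher side, Mapre2, a protein of growing microtubule ends, was at 9.59 ± 3.98 in MPTP and 24.1 ± 0.563 FPKM in running mice (log2 fold change 1.31, SE 0.22, limma adjusted p = 0.505). Knop1 was at 2.84 ± 0.233 and 4.49 ± 0.253, Trim23 at 9.76 ± 0.889 and 12.8 ± 0.8999, Fam162a at 17.5 ± 1.48 and 22.5 ± 1.63 and Snrpert at 2.27 ± 0.167 and 3.36 ± 0.288 FPKM. On the lower side Adprhl2 was at 6.27 ± 0.650 and 3.72 ± 0.337 FPKM and Myl12b at 5.05 ± 0.394 and 2.96 ± 0.511 FPKM, with neither past the threshold. Knop1 and Fam162a share exonic bases with neighbouring genes and are uncertain. The Myl12b entry, ENSMUSG00000117098, shares 739 exonic bases with another entry of that symbol and 462 with Myl12a. Its values are thus uncertain and may not stand for Myl12b as a whole. The values of 1283 genes (8.02%) did not overlap between the groups, where chance gives 10%, and 799.85 genes are expected at an unadjusted p under 0.05. Of 47 lists, 19 passed camera (8 higher, 11 lower), 0 with an estimated correlation and 0 in fry. The count of 0 genes became 25 without MPTP replicate 1, 2 without MPTP replicate 2 (Dnase2a and Bpifb9b), 1 without MPTP replicate 3 (Mapre2), and 1 without exercise replicate 1 (Tmem56) and 1 without exercise replicate 2 (Zbtb9). All of these but Mapre2 were named after their values were seen. Igfbp2 was past the threshold with no filter on mean FPKM (limma adjusted p = 0.0305), at a mean of at least 5 FPKM (0.0328), with values rescaled to the same sum (0.0476), with array weights (0.0420) and without MPTP replicate 1 (0.0364). Over its alternatives the adjusted p ranged from 0.0305 to 0.744.

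The reversal the study's title implies is a change with MPTP that exercise turned back. At an adjusted p under 0.05 in both comparisons 0 genes met it (limma), and at 0.1 it was met by 1 gene, Igfbp2, which rose with MPTP and lay at 14.7 ± 0.408 FPKM in running mice against 13.3 ± 0.731 in vehicle mice. At an unadjusted p under 0.05 in both, 199 genes met it, 162 higher with MPTP and lower with exercise and 37 the other way, and 2 genes moved the same way in both. Independent comparisons with those numbers of genes would share 12.04 and 2.62. The MPTP libraries enter both comparisons, however, and with no effect at all simulated groups gave a mean of 169.3 such genes, with 1171 at the highest of 50 draws. Log2 fold changes of the 2 comparisons correlated across genes at −0.45, against −0.47 in simulations with no effect (−0.90 to 0.21, 1000 draws), with a covariance of −0.0179 against −0.0223. The opposite movement was thus no larger than in these simulations with no effect. They drew libraries without regard to replicate number, and same-numbered MPTP and vehicle libraries deviated together. How far that changes the value with no effect was not tested. With 3 MPTP libraries no split leaves at least 2 in each part. Without MPTP replicate 1 the count at an adjusted p under 0.05 became 24. Over the 3 groups together 1 gene, Igfbp2, passed limma's F-test (adjusted p = 0.0426). That call ended with the replicate number as a block, where 0 genes passed, and 29 passed without MPTP replicate 1.

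The comparison of MPTP plus exercise with vehicle asks how far mice with both treatments stood from mice given saline. No gene passed (limma, 1047 at an unadjusted p under 0.05, 499 higher and 548 lower, where chance gives 799.85), and the smallest adjusted p was 0.753. Ribosomal protein genes were higher in all 40 cases (median 0.23, camera adjusted p = 4.78e-17, adjusted p = 0.693 with an estimated correlation) and oxidative phosphorylation genes in 46 of 47 (median 0.20, camera adjusted p = 2.41e-16, adjusted p = 0.693 with an estimated correlation). Rpl38 was at 112 ± 4.22 in vehicle and 147 ± 17.5 FPKM in running mice and Cox5b at 64.8 ± 5.53 and 80.5 ± 0.982 FPKM. Heat shock genes were higher in all 18 cases (median 0.14, camera adjusted p = 0.000138, adjusted p = 0.693 with an estimated correlation). Hsp90aa1 was at 249 ± 13.4 and 291 ± 14.1 FPKM. In these 3 lists no gene passed when adjusted over the list alone (limma, 14, 14 and 1 at an unadjusted p under 0.05). The FPKM sum of a library was 318416 to 319431 in vehicle and 331121 to 344049 in running mice. Over 25 settings, rescaling to the same sum included, the lowest means were 0.13 for ribosomal protein and 0.12 for oxidative phosphorylation genes. The heat shock mean of 0.16 went to 0.10 without exercise replicate 2, 0.25 without vehicle replicate 2 and 0.11 without vehicle replicate 3.

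Blood cell genes were lower in all 8 cases against vehicle (median −1.70, camera adjusted p = 5.05e-09, adjusted p = 0.524 with an estimated correlation). There, 7 passed when adjusted over the list alone and 0 over all genes tested. S100a9 was at 3.72 ± 1.52 and 0.810 ± 0.603 FPKM and the globin gene Hba-a1 at 45.5 ± 52.9 in vehicle, where replicate 3 alone reached 107, and 5.40 ± 4.79 FPKM in running mice. Mural genes were lower in 19 of 20 cases (median −0.33, camera adjusted p = 2.24e-06, adjusted p = 0.693 with an estimated correlation). There, 2 passed when adjusted over the list alone, Vtn (27.4 ± 3.01 and 17.9 ± 1.36 FPKM) and Pdgfrb, and 0 over all genes tested. The mean shift of the mural list went from −0.35 to −0.17 without vehicle replicate 2 (camera adjusted p = 0.0181), and that of the blood list from −1.59 to −1.02 without vehicle replicate 3. Endothelial genes were lower in 15 of 20 (median −0.15, camera adjusted p = 0.000812, adjusted p = 0.731), with a mean of −0.15, and of −0.10 without exercise replicate 1. Interferon genes remained higher in running than in vehicle mice in 26 of 28 cases (median 0.26, camera adjusted p = 4.22e-06, adjusted p = 0.731 with an estimated correlation). The estimated correlation uses all 9 libraries, the MPTP libraries with their score SD of 0.51 included. The list scores were 1.47 ± 0.03 in vehicle and 1.76 ± 0.03 in running mice and did not overlap (1.43 to 1.49 and 1.72 to 1.78). Ifi27 was at 10.6 ± 0.633 and 16.2 ± 2.18 and Oas1a at 0.387 ± 0.178 and 0.941 ± 0.173 FPKM. Antigen presentation genes were higher in 13 of 16 (median 0.16, camera adjusted p = 0.00291, adjusted p = 0.731). That call ended without exercise replicate 2 (0.0834), without MPTP and exercise replicates 2 (0.0649) and with array weights (0.0550), and the mean of 0.16 went to 0.10 without exercise replicate 2 or vehicle replicate 3 and 0.24 without vehicle replicate 2. Activated microglia genes were higher in 15 of 20 (median 0.08, camera adjusted p = 0.00416, adjusted p = 0.524). That call ended at a mean of at least 5 FPKM (0.0756).

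Neighbouring regions differed here too. Hippocampus and cortex genes were higher in running than in vehicle libraries in 17 of 20 cases (median 0.36, camera adjusted p = 0.0132, adjusted p = 0.784 with an estimated correlation). The mean turned to −0.06 without vehicle replicate 1 (camera adjusted p = 0.812). The call also ended without exercise replicate 1 (0.183) or 3 (0.197), where the mean of 0.38 went to 0.19 and 0.23. It went to 0.72 without exercise replicate 2 and 0.64 without vehicle replicate 2. The call ended as well at a mean of at least 5 FPKM (0.317), with quantile normalization (0.0544), with samples shifted to the same median (0.0561) and with the choroid plexus covariate (0.157). Cholinergic genes (5 of 6 higher, camera adjusted p = 0.0256, adjusted p = 0.731 with an estimated correlation) lost their call without exercise replicate 2 (0.463, mean 0.11 against 0.48), MPTP replicate 2 (0.0546), vehicle replicate 2 (0.0690), vehicle replicate 3 (0.105) or MPTP and exercise replicates 2 (0.498), with samples shifted to the same median (0.0618) and with array weights (0.125). Border macrophage genes (5 of 5 lower, camera adjusted p = 0.0256, adjusted p = 0.524) lost theirs without exercise replicate 2 (0.143) or 3 (0.0588), MPTP replicate 2 (0.0546), vehicle replicate 2 (0.0817) or MPTP and exercise replicates 2 (0.219). That call also ended with no filter on mean FPKM (0.135, mean −0.11 against −0.24), with quantile normalization (0.0544), with array weights (0.0550) and with the choroid plexus covariate (0.0506). Non-polyadenylated RNAs (8 of 10 higher, camera adjusted p = 0.0313, adjusted p = 0.731) lost theirs without exercise replicate 1 (0.131) or vehicle replicate 2 (0.629), where the mean of 0.33 went to 0.15 and 0.13. Without vehicle replicate 1 it went to 0.53. That call ended as well with samples shifted to the same median (0.0627) and with the choroid plexus covariate (0.104). The mitochondrially encoded transcripts (10 of 13 higher, median 0.10, mean 0.07, camera adjusted p = 0.00659, adjusted p = 0.731) turned direction when values were rescaled to the same sum (mean −0.02) or quantile normalized (mean −0.05). Without mt-Atp6 these 3 means were 0.12, 0.03 and −0.00493. With values rescaled to the same sum the turn thus rested on mt-Atp6, while quantile normalization holds these transcripts near 0 by construction. The call on all 13 was lost without exercise replicate 2 (0.0767, mean 0.03), without MPTP and exercise replicates 2 (0.0512) and with no filter on mean FPKM (0.268). In all, 14 of 47 lists passed camera (10 higher, 4 lower), 0 with an estimated correlation and 0 in fry. Ferroptosis suppressors (16 of 29 higher, camera adjusted p = 0.452), drivers (camera adjusted p = 0.585) and dopaminergic genes (12 of 21 higher, camera adjusted p = 0.426) did not pass.

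The single genes with the smallest p against vehicle, none past the threshold (limma adjusted p = 0.753 for each), were on the higher side Mapre2 (9.50 ± 1.01 and 24.1 ± 0.563 FPKM), Mrpl32 (1.56 ± 0.167 and 2.79 ± 0.263), Knop1, Snrnp25 (6.17 ± 0.0787 and 10.01 ± 1.56) and Dpm3 (5.16 ± 0.370 and 7.21 ± 0.599). On the lower side they were Cxcl12, a chemokine of vessels and meninges (7.13 ± 0.321 and 4.88 ± 0.196), Vtn, Cux2 (5.55 ± 0.423 and 3.90 ± 0.131), S100a9 and Reck (3.01 ± 0.164 and 2.07 ± 0.133 FPKM). The values of 2492 genes (15.6%) did not overlap between the groups, where chance gives 10%. The count of 0 genes became 1 without exercise replicate 1 (Tmem56) or 2 (Zbtb9), and 2 without vehicle replicate 1 (Pdxp and Prkacb) or 2 (Gm28048 and B3gnt2), all named after their values were seen.

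The study's title names 2 genes of lipid peroxidation. Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614, minus strand, GRCm38), a subunit of the transporter that imports cystine for glutathione synthesis, was at 3.49 ± 0.607 in vehicle, 3.40 ± 0.314 in MPTP and 2.92 ± 0.666 FPKM in running mice. Its log2 fold change was −0.02 (SE 0.15) with MPTP and −0.18 (SE 0.15) with exercise, smaller than or close to its standard error (exact two-sided permutation p = 1 and 0.4 with n = 3 per group), and they ranged from −0.14 to 0.05 and from −0.29 to −0.04 when 1 library was left out. Alox12 (ENSMUSG00000000320, chromosome 11, 70241457 to 70255353, minus strand), a lipoxygenase of arachidonic acid, lay under the filter on mean FPKM. It was at 0.185 ± 0.0125 in vehicle, 0.180 ± 0.0458 in MPTP and 0.0799 ± 0.0230 FPKM in running mice, which is about 5 to 25 fragments per library. All 3 libraries of running mice (0.0593 to 0.105 FPKM) lay below the other 6 libraries. The exact two-sided permutation p was 0.9 for MPTP against vehicle (n = 3 each), and 0.1 for running mice against either group, which is the smallest p that this permutation of 3 against 3 can give. In limma with no filter on mean FPKM its log2 fold change was −0.13 (SE 0.03) against MPTP and −0.13 (SE 0.03) against vehicle, with adjusted p = 1 and 0.862 over 35406 genes (unadjusted p = 0.00562 and 0.00427). The labels name whole tissue, in which the share of either transcript that comes from microglia is not measured.

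**Figure D3:**
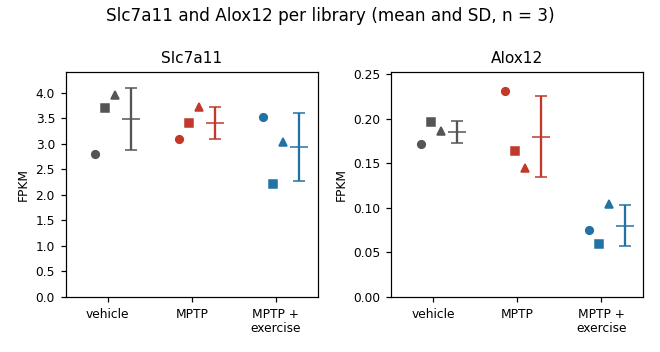
FPKM (y axis, from 0) of Slc7a11 and Alox12 per library by group; circle, square and triangle are replicates 1, 2 and 3, and the bar with error bars is the mean and SD of 3 libraries. Slc7a11 values overlap between all groups, and the Alox12 values of the running mice, 0.0593 to 0.105 FPKM, lie below the others.

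Markers of dopaminergic neurons did not separate the groups. Th (chromosome 7, 142892752 to 142931128, minus strand, GRCm38), the rate-limiting enzyme of dopamine synthesis, was at 7.97 ± 6.75 in vehicle, 6.68 ± 5.45 in MPTP and 4.90 ± 2.06 FPKM in running mice (n = 3 each; exact permutation p = 0.8 for MPTP against vehicle and 0.9 for running against MPTP). Slc6a3 (chromosome 13, 73536747 to 73578672, plus strand) was at 3.40, 1.41 and 10.8 FPKM in the vehicle libraries, 2.75, 0.0377 and 14.4 in the MPTP libraries and 0.149, listed at 0 and 10.6 in the running mice. Slc18a2, the vesicular monoamine transporter, was at 5.58 ± 2.49, 6.53 ± 4.68 and 7.47 ± 2.29 FPKM and Ddc, which makes dopamine from L-DOPA, at 6.34 ± 2.61, 7.33 ± 4.74 and 8.27 ± 1.92 FPKM. The values of the 3 groups overlapped for all 4 genes, and with MPTP against vehicle the log2 fold changes of all 4 genes turned sign when 1 library was left out, with ranges of −0.80 to 0.37 for Th, −1.34 to 0.60 for Slc6a3, −0.46 to 0.66 for Slc18a2 and −0.37 to 0.58 for Ddc. Markers of nearby regions spread as widely. Prkcd, high in thalamus, ranged from 2.40 to 48.3 FPKM, the striatal receptor gene Drd2 from 1.61 to 14.9, Neurod6 of cortex and hippocampus from 1.43 to 54.0, and the choroid plexus gene Ttr from 18.5 in exercise replicate 2 to 2010.5 in MPTP replicate 3. These 4 genes were chosen after their values were seen.

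**Figure D4:**
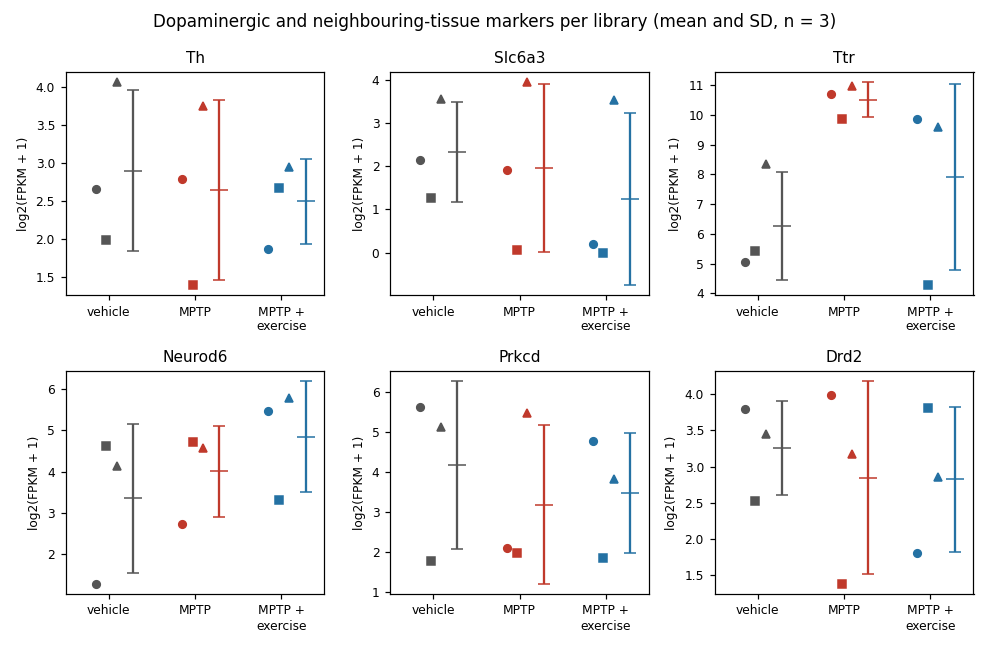
Log2(FPKM + 1) (y axis) of Th, Slc6a3, Ttr, Neurod6, Prkcd and Drd2 per library by group; circle, square and triangle are replicates 1, 2 and 3, and the bar with error bars is the mean and SD of 3 libraries. Slc6a3 ranges from listed at 0 to 14.4 FPKM and Ttr from 18.5 to 2010.5 FPKM.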

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

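Of the results for named genes under alternatives, 905 kept their direction and side of the threshold, 21 lost and 12 gained a call and 35 turned direction. For lists these numbers were 1028, 193, 0 and 12. Igfbp2 and H2-K1 kept their direction between MPTP and vehicle in all 22 settings. Fits without a library or with a covariate have fewer degrees of freedom, and otherwise the cause was not tested. Below, the gene counts are those past the threshold, with 2 for MPTP against vehicle, 0 for exercise against MPTP, 0 for exercise against vehicle, 1 for any group and 0 for the reversal in the planned fit. With no filter on mean FPKM MPTP against vehicle had 3 genes (Gzmb, Gm24674 and Igfbp2, without H2-K1), exercise against MPTP 3, any group 3 and the reversal 3. At a mean of at least 5 FPKM exercise against MPTP had 1, any group 2 and the reversal 1, with 7 lists against 14 for exercise against vehicle. With values rescaled to the same sum exercise against MPTP and the reversal had 1 each, mitochondrially encoded transcripts turned to −0.005428 (MPTP against vehicle) and −0.0168 (exercise against vehicle), autophagy and lysosome to −0.002086 and Ddc to −0.0184 (MPTP against vehicle). With quantile normalization any group had 2, mitochondrially encoded transcripts were at −0.0308 and −0.0482 in the same comparisons and Slc18a2 at 0.0290 with MPTP. With samples shifted to the same median any group had 0 and Slc18a2 was at 0.006421. No scaling moved the median log2 fold change of all genes beyond −0.09. With only the 2 groups compared MPTP against vehicle had 0, and with no mean-variance trend any group had 0. With array weights exercise against MPTP and the reversal had 1 each, Th was at 0.14, Slc6a3 at 0.14 and Slc18a2 at 0.42 with MPTP, and Slc18a2 at −0.007741 with exercise. At an unadjusted p under 0.05 and an absolute log2 fold change of at least 1 the counts were 66, 30 and 21 and the reversal 21. At an adjusted p under 0.1 exercise against MPTP had 1, any group 2 and the reversal 1. The lists moving were 0, 0 and 0 with an estimated correlation and 2, 0 and 0 in fry.

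The labels do not say whether the numbers pair mice, and 4 of 9 libraries resembled their own number best. Every number occurs once in each group, so chance alone gives some such matches, and the 4 are not read as pairing. MPTP and vehicle libraries of the same number deviated together in all 3 pairs (0.25, 0.33 and 0.11). With number as a replicate block MPTP against vehicle had 3 genes (adjusted p = 0.0415 each), with Enpp2 added, and any group 0, and no other call of a named gene or list that passed changed. Without MPTP and exercise replicates 2 the counts were 0, 1 and 2, cholesterol synthesis turned to −0.001191 and Slc18a2 to −0.45 and Ddc to −0.21 with exercise, and Th was at 0.37, Slc6a3 at 0.60 and Slc18a2 at 0.66 with MPTP. With the choroid plexus covariate MPTP against vehicle and any group had 0, oxidative phosphorylation was at −0.0673, cholesterol synthesis at −0.0774, Th at 0.62 and Slc6a3 at 1.23 with exercise, and Ddc at −0.46 with MPTP. With the hippocampus covariate MPTP against vehicle had 3 genes, with Mir5117 added (adjusted p = 0.0334), any group had 0, exercise against vehicle 22 lists, and Slc18a2 was at 0.16 with MPTP. A list was not tested with its own score as the covariate. These last 3 alternatives were added after the data were seen.

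Leaving out 1 library at a time gave 0 to 32 genes for MPTP against vehicle, 0 to 25 for exercise against MPTP, 0 to 2 for exercise against vehicle, 0 to 29 for any group and 0 to 24 for the reversal, and 13 to 21, 17 to 23 and 12 to 18 lists. With MPTP the ranges were −0.14 to 0.0546 for Slc7a11, −0.80 to 0.37 for Th, −1.34 to 0.60 for Slc6a3, −0.46 to 0.66 for Slc18a2 and −0.37 to 0.58 for Ddc. For exercise against MPTP they were −0.78 to 0.40 for Th, −1.87 to 0.27 for Slc6a3, −0.27 to 0.86 for Slc18a2, −0.20 to 0.74 for Ddc, −0.0108 to 0.15 for oxidative phosphorylation, −0.001711 to 0.15 for ribosomal proteins and −0.0173 to 0.18 for cholesterol synthesis. For exercise against vehicle they were −0.0572 to 0.72 for hippocampus and cortex and −0.86 to 0.17 for Th.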

Other observations

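Genes outside the lists that passed add detail. Enpp2, which encodes the secreted enzyme autotaxin and is expressed in choroid plexus as well as in oligodendrocytes, was at 66.4 ± 7.57 FPKM in vehicle, 179.6 ± 40.3 in MPTP and 100.3 ± 26.3 in running mice (n = 3 each; MPTP against vehicle log2 fold change 1.40, SE 0.22, limma adjusted p = 0.252, or 0.0415 with the replicate number as a block). It was the 1 gene of the myelin list past the threshold when adjusted over the list alone, with 0 over all genes tested, and the list itself did not move (9 of 24 higher, median −0.05, camera adjusted p = 0.907, with the test pointing up). Astrocyte genes did not move either (9 of 18 higher, camera adjusted p = 0.857, median 0.003 and mean −0.03). Their gap junction gene Gja1 was at 25.1 ± 1.87 in vehicle, 15.9 ± 9.06 in MPTP and 24.2 ± 0.620 FPKM in running mice. Vegfa was at 11.7 ± 0.334 FPKM in vehicle, 15.2 ± 0.921 in MPTP and 11.9 ± 0.573 in running mice, and was the 1 gene of the exercise and neurotrophic list past the threshold between MPTP and vehicle when adjusted over the list alone, with 0 over all genes tested (camera adjusted p = 0.857 for the list).

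The tests on refitted splits, except that on lists moving in opposite directions, were fixed before the result was seen, and all other tests of this section were chosen after it. The blood, paralog, vessel, Slc6a3 and chance ordering criteria were revised after the values were seen. With 10 splits of 6 libraries a share under 0.05 cannot be reached. Of the splits for MPTP against vehicle 3 gave at least the real 2 genes (highest other 5) and 5 at least the real 17 lists (highest other 20). Among the 4 splits that part all 3 same-numbered pairs, the real one included, the highest other had 1 gene and 16 lists, while the others part 1 pair. With only 4 splits a share under 0.05 cannot be reached either, so the real one ranking first there decides nothing. For exercise against MPTP 10 gave at least the real 0 genes (highest other 4) and 3 at least the real 19 lists (highest other 23). For exercise against vehicle 10 gave at least the real 0 genes (highest other 2) and 3 at least the real 14 lists (highest other 19). Over 3 groups 57 of 100 splits gave at least the real 1 gene (highest other 216), and for the reversal at an unadjusted p under 0.05 27 of 100 gave at least the real 199 genes (highest other 1486), so chance is not excluded for either. In the same arrangements 36 of 100 gave at least the real 9 lists that passed camera in opposite directions with MPTP and with exercise (highest other 14), so chance is not excluded for the lists either. The split with 1486 genes had vehicle 1, MPTP 1 and exercise 2 as its middle group, the libraries at −26.3, −14.0 and −20.3 on the first principal component (27.1% of variance, the others from −0.85 to 21.2), which points to a structure of the samples across the groups. These libraries had the highest myelin list scores (5.76 to 5.88, the others 5.16 to 5.44). Their hippocampus and cortex scores were the lowest (2.84 to 3.52, the others 3.89 to 4.48). Tissue content thus differed along this structure.

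Interferon and antigen presentation genes and Igfbp2 were higher in MPTP mice, in which choroid plexus genes were higher too. With the choroid plexus score as a covariate the mean shift of the 44 interferon and antigen presentation genes was 0.855 (SE 0.299). Without it the shift was 0.836 (SE 0.201). For Igfbp2 the shift was 1.01 (SE 0.0933) against 0.91 (SE 0.08). The covariate thus lessened neither shift. For Igfbp2 choroid plexus tissue in the dissections did not account for the change. Its call was lost with the fewer degrees of freedom (limma adjusted p = 0.109). For the 44 genes the SE is too wide to exclude that such tissue gave part of the shift. Reads moved between class I paralogs would leave their sum as it was, but the summed fragments of 21 class I H2 genes shifted by 1.04 (SE 0.172), against a mean of 1.11 for the 6 in the antigen presentation list. A chance ordering of the 9 libraries stays open. The MPTP mean differed from that of the other 6 at an exact two-sided permutation p of 0.0357 in the interferon score. In that score MPTP replicate 1, at 1.76, lay within the 1.72 to 1.78 of the running mice. For the antigen presentation score the permutation p was 0.0119. By the same test the choroid plexus score was at 0.0357 too, and activated microglia and complement at 0.0119. Of 47 lists 6 were under 0.05, where 2.35 are expected. As 84 splits give no p smaller than 0.0119, the design nearly fixed that none would pass when adjusted over 47 lists. The adjusted p was 0.336 for the interferon and 0.187 for the antigen presentation score. That MPTP raised an interferon response and running lessened it is a hypothesis drawn from the same data, which no test here decides.

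Endothelial and mural genes were lower in running than in MPTP mice in 40 of 40 cases, as were blood cell genes. With the blood cell score as a covariate the mean shift of the 40 genes was −0.383 (SE 0.133). Without it the shift was −0.317 (SE 0.107), so the covariate did not lessen it. The blood score was 4.17 in vehicle replicate 3 against 2.33 and 2.58 in the other vehicle libraries. With that 1 library weighing on the slope and an SE this wide, less residual blood is not excluded. A lower share of vessel-bearing tissue would shift both lists alike. The mural shift less the endothelial shift was −0.130 (SE 0.148) over libraries, from the list scores. Over genes, from ratios of group mean FPKM, it was −0.207 (SE 0.0798). That SE treats coexpressed genes as independent and is too small. The 2 versions therefore do not decide, and this explanation stays open.

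Slc6a3 spread widely within every group, with an SD of log2(FPKM + 1) of 1.16 in vehicle, 1.95 in MPTP and 1.99 in running mice. The median within-group SD of region scores was 4.78 times that of glial and endothelial scores (0.533 against 0.111), which goes with a dissection that caught different regions. The 2 sets overlapped, with mature oligodendrocytes and myelin at 0.318 and cerebellum and pons at 0.223. Some region lists held as few as 5 tested genes, which can widen an SD, while hippocampus and cortex, with 20, was at 0.604. Unequal loss of neurons to MPTP would make the vehicle SD the smaller. The ratio of vehicle to injected groups was 0.588 (95% interval 0.180 to 3.68), which leaves this open.

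Single libraries held transcripts of other tissues. In vehicle replicate 3 the hypothalamic genes Pmch and Hcrt were at 66.2 and 14.4 FPKM, the olfactory genes Omp and S100a5 at 9.34 and 25.1 and the globin gene Hbb-bs at 157.0 FPKM, while Tph2 of serotonergic neurons was at 0.124 FPKM. Omp and S100a5 were also at 4.87 and 3.29 FPKM in MPTP replicate 1. The pituitary gene Gh was at 8.22, 17.1 and 15.2 FPKM in MPTP replicates 1 and 3 and exercise replicate 1, and the hindbrain gene Hoxb5 at 10.01 FPKM in exercise replicate 2. The mitochondrial gene mt-Atp6 was at 1905 FPKM in MPTP replicate 2 and 1964 in exercise replicate 1 against 7369 to 9616 in the others, while mt-Atp8, which shares 43 bases with it, was at 9208 to 13112 in all. Kctd12 was listed at 0 in MPTP replicate 1 and at 7.81 FPKM or more in the other 8, as 1 of 4 such genes.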
